A study of Mus musculus with 16 samples.

How the data were processed

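Extracellular vesicles were collected from mouse bronchoalveolar lavage fluid, their RNA was isolated with a QIAGEN miRNA kit, and small RNA libraries were sequenced on an Illumina protocol. There were 16 libraries in 4 groups of 4: normal (saline-treated) wild type, normal Sdc1 knockout, bleomycin wild type and bleomycin Sdc1 knockout. The bleomycin samples were recorded with a bleomycin day of 21. The labels do not state that each library came from a different mouse, so every p-value measures only the spread between these libraries. Groups were taken from the sample titles, and all 16 columns matched a sample.

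The authors deposited 1 table of CPM (counts scaled to a common total per library) for 1907 mature mouse miRNAs, of which 1358 were above 0 in at least 1 library. Each deposited column sums to the same total over these miRNAs, so a value is a share of miRNA reads and not an amount per volume of lavage. Every value was a whole multiple of its column's smallest step, and 100% of the values divided by that step lay within 0.001 of a whole number, which gave whole reads. The labels name Bowtie2 2.2.3 and genome build GRCh38, a human build, without giving the role of either. The read counter, adapter trimming and miRBase release are not given in the sources used here.

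Recovered depth ran from 1094908 to 12837837 reads per library, so 1 read was between 0.0779 and 0.913 CPM. A count of 0 allows up to 3 reads, which is 0.234 CPM in the deepest library and 2.74 CPM in the shallowest. Such limits and the counting intervals below cover counting error only, because amplified reads are not independent molecules.

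The miRNAs at 10 CPM or more in at least 4 of the 16 libraries were tested. These were 325 miRNAs holding at least 99.9% of the CPM of every library. Log2(CPM + 5) values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) with 4 group means and 12 residual degrees of freedom. Fold changes are therefore of CPM + 5, which shrinks those of miRNAs under about 50 CPM. There were 7 comparisons: bleomycin minus normal in each genotype, knockout minus wild type in each condition, the interaction, and both effects averaged. Benjamini-Hochberg adjustment was made within each comparison at 0.05.

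Before the data were examined, 16 lists were fixed: 4 miRNAs recalled from memory of the study's publication, and erythrocyte, leukocyte, miR-200 family, other epithelial, miR-34 and miR-449 family, mesenchymal, endothelial, liver and muscle, miR-29 family, let-7 family, miR-30 family, miR-17-92 clusters, miR-322 and miR-503 cluster, injury and inflammation, and Dlk1-Dio3 cluster. The membership of the first was not checked against the publication, and if the study chose it on these libraries, as recalled, it is not independent evidence of its direction. Lists were tested with limma's fry, which asks whether members move on balance one way, with adjustment over the 16 lists of a comparison. Camera with an estimated correlation between members, which compares a list with the other miRNAs, was the alternative. Members were counted by their own call over the 325 miRNAs and, in the words used below, adjusted over the list alone.

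The rule for named miRNAs was also fixed before the data were examined. In each of the 4 pairwise comparisons it took the 10 largest rises and 10 largest falls past the threshold with a mean of at least 50 CPM. Where fewer than 5 passed it added the 5 smallest p, and the interaction and the averaged effects were given by their 5 smallest p. The 8 most abundant miRNAs, the 4 from the publication and up to 4 members per list were always included. The neighbouring genes of the miR-322 and miR-503 cluster and the GC content of precursors came from the mouse reference annotation and sequence.

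Per library, 6 measures were compared with a two-sided exact permutation test over the 70 arrangements of 4 against 4, whose smallest possible p is 0.029. On simulated data with 60 of the 325 miRNAs changed in each of 20 simulations, the test recovered 16.2 to 19.2% of 2-fold and 74.8 to 76.2% of 4-fold changes, and 3.65 to 5.32% of its calls were false. In the same simulations fry called the changed list in 100% of runs and an unchanged list in 0 to 15%. Each simulated miRNA was drawn independently, without the differences that many miRNAs of the real libraries share. These rates, of limma and of fry, therefore need not hold for the real libraries.

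Alternatives were other pseudocounts (1 and 20), other filters (none and 100 CPM), median-of-ratios scaling, quantile normalization, a fit of only the 8 libraries compared, the replicate number as a block, limma array weights, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, and leaving out each library in turn. Chosen after seeing the data were fits without the 3 normal libraries with the fewest reads, without bleomycin wild-type libraries 1 and 3, with log2 reads as a covariate, with CPM recomputed without miR-21a-5p, and with identical profiles counted once. Among the tested miRNAs 8 pairs had identical values in every library and 18 pairs, these included, had a log2 ratio with an SD under 0.1. Examples are miR-142a-3p with miR-142b and miR-21a-5p with miR-21c, so such a pair is 1 signal. The tested erythrocyte members other than miR-451a are copies or near copies of 1 miR-486 signal. The endothelial list is made of such miR-126 pairs, and the mesenchymal list holds the pair miR-199a-3p and miR-199b-3p. Single libraries far from the rest of their group were sought with Dixon's ratio, on log2(CPM + 5) for the named miRNAs and on 7 measures per library (reads, miRNAs detected, miRNAs at 10 CPM, share of the top 10, and the erythrocyte, leukocyte and liver and muscle shares). Expression of Sdc1 itself is not measured by a miRNA table, so the knockout was not checked.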

Results

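The series profiled the miRNA cargo of extracellular vesicles in lung lavage, in mice with and without syndecan-1 and with and without bleomycin. Syndecan-1, the product of Sdc1, is a heparan sulfate proteoglycan of epithelial cell surfaces, and bleomycin is a drug that injures the lung and is used to model fibrosis. There were 4 libraries in each of 4 groups: normal wild type, normal knockout, bleomycin wild type and bleomycin knockout. Depth ran from 1094908 to 12837837 reads, with means of 5344430 reads in normal wild type, 9366220 in normal knockout, 4118010 in bleomycin wild type and 5004910 in bleomycin knockout. Values below are CPM means with their SD, and log2 fold changes with their standard error (SE), each for n = 4 libraries per group.

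A few miRNAs filled most of each profile. The 10 most abundant miRNAs of a library took between 57.9 and 77.2% of its reads. Averaged over the 16 libraries, miR-21a-5p took 14.9%, miR-30d-5p 13.1%, let-7i-5p 6.34%, miR-30a-5p 6.31%, let-7c-5p 5.19%, miR-143-3p 4.67%, miR-26a-5p 4.53% and let-7f-5p 3.61%. The first principal component held 44.6% of the variance. Bleomycin libraries lay higher on it, between -0.597 and 15.1, than normal ones, between -17.1 and 2.08, with an overlap of bleomycin wild-type library 3 and normal knockout libraries 1 and 3. Correlation of log2 values across miRNAs between libraries of 1 group ran from 0.897 to 0.991.

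**Figure D1:**
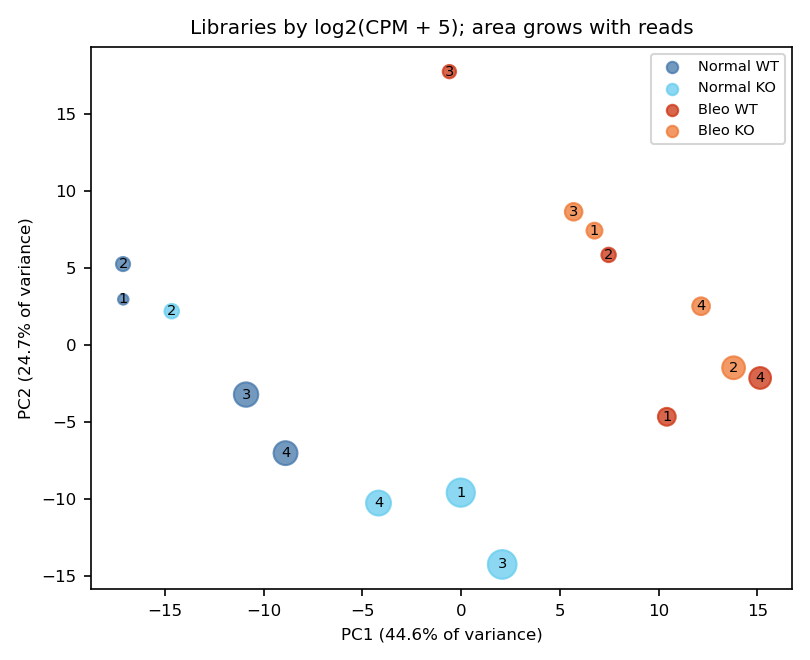
Principal components 1 (44.6% of variance) and 2 (24.7%) of log2(CPM + 5) for the 16 libraries, coloured by group and numbered by replicate, with the area of each point growing with its reads. Bleomycin wild-type library 3 (component 1, -0.597) lies below normal knockout libraries 1 (-0.0206) and 3 (2.08) on the first component.

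Libraries of the same condition with more or fewer reads differed in named miRNAs. In the normal condition the 3 samples with the fewest reads had more miR-375-3p than the 5 deeper samples (log2 difference 3.28, SE 0.55), more miR-34b-3p (2.66, SE 0.60) and more miR-486a-5p (2.93, SE 0.87), and less miR-199b-5p (-2.31, SE 0.63) and miR-126a-3p (-2.03, SE 0.54). These samples were grouped after the depths were seen, and the miRNAs were chosen after their values were seen. Of the measures per library, the share of reads in the leukocyte list had the smallest p, with 0.233% ± 0.0521 (SD, n = 4) in normal knockout and 0.383% ± 0.0969 in bleomycin knockout (exact permutation p = 0.0571, adjusted p = 1 over 24 tests). The erythrocyte share was 0.450% ± 0.475 in normal wild type and 0.823% ± 1.15 in bleomycin wild type, and the liver and muscle share 0.223% ± 0.210 and 0.111% ± 0.0956, neither past the exact permutation test (adjusted p = 1 for each).

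The first comparison asked how bleomycin changed the vesicle miRNAs of wild-type lavage. MiR-21a-5p, widely described as rising in injured and fibrotic tissue, rose from 3.91% ± 1.72 (SD, n = 4) of all miRNA reads to 25.4% ± 7.92, a log2 fold change of 2.76 (SE 0.33, limma adjusted p = 1.61e-05). Every bleomycin library lay above every normal one. MiR-199a-5p, made in mesenchymal cells, rose 10.5-fold (log2 3.39, SE 0.45, adjusted p = 3.87e-05), from 447 ± 223 to 4577 ± 1580 CPM. MiR-132-3p and miR-212-5p, which are processed from neighbouring hairpins of 1 transcript, rose by 2.82 (SE 0.39, adjusted p = 4.24e-05) and 2.71 (SE 0.32, adjusted p = 1.3e-05). MiR-30d-5p, a member of a family abundant in lung epithelium and the most abundant miRNA of the normal libraries, fell by 2.32 (SE 0.39, adjusted p = 0.000265), from 240487 ± 37661 to 54723 ± 26723 CPM. MiR-200a-3p, of a family that maintains epithelial identity, fell by 2.68 (SE 0.52, adjusted p = 0.000748), from 46155 ± 11483 to 9493 ± 7437 CPM.

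Of the other abundant miRNAs let-7i-5p rose by 1.92 (SE 0.33, adjusted p = 0.000268), while let-7c-5p (0.34, adjusted p = 0.418), let-7f-5p (1.07, 0.12), miR-143-3p (-0.54, 0.354) and miR-26a-5p (-0.10, 0.838) were not called. Other large rises in wild type were those of miR-218-5p (3.40), miR-184-3p (3.40), miR-7b-5p (2.67), miR-653-5p (2.57) and miR-344-3p (2.38), each higher in all 4 bleomycin libraries than in any normal one. MiR-451a of red cells rose by 2.38 (SE 0.84, adjusted p = 0.0344), higher in 3 of 4. Large falls were those of miR-34b-3p (-3.51), miR-205-5p (-3.50), miR-1298-5p (-3.14), miR-503-3p (-3.13), miR-375-3p (-3.12), miR-1264-3p (-2.84), miR-223-3p (-2.72), miR-351-5p (-2.69) and miR-92b-3p (-2.56). Without the 3 normal samples of low depth, in which miR-34b-3p and miR-375-3p were high, the falls of miR-205-5p (adjusted p = 0.0909, 0.000142 to 0.0909 over the alternatives), miR-375-3p (0.163, 2.03e-05 to 0.163), miR-1264-3p (0.176) and miR-92b-3p (0.22) were no longer called, while that of miR-34b-3p was. MiR-451a was not called without normal library 1, 2 or 4 or bleomycin library 2, 3 or 4 (adjusted p 0.0569 to 0.122). MiR-375-3p and miR-92b-3p were not called without normal library 1 or 2 or bleomycin library 4 (0.0534 to 0.0682 and 0.0692 to 0.0794). The same held for miR-1264-3p without normal library 1 or 2 or bleomycin library 1, 2 or 4 (0.0502 to 0.0947). Some folds moved by more than 1.5 times but stayed called: without bleomycin library 3 the log2 change was -4.20 for miR-34b-3p, -4.47 for miR-205-5p, -3.94 for miR-375-3p, -3.47 for miR-1264-3p and -3.25 for miR-92b-3p. Likewise it was -2.84 for miR-205-5p and -2.10 for miR-223-3p without bleomycin library 1, and -2.01 for miR-351-5p without bleomycin library 4. In total limma called 112 of 325 miRNAs, 65 up and 47 down, and edgeR called 137, 79 up and 58 down. The count was 74 without normal library 2 and 67 without the 3 normal samples of low depth. That last fit leaves only libraries 3 and 4 in normal wild type, so calls it ended can reflect fewer libraries as well as depth. Before miR-21a-5p was removed from the total, all 325 miRNAs had a median log2 change of -0.004. With it removed, they moved up by a median of 0.35 and the split was 85 up and 34 down. Without bleomycin library 3 it was 45.5% up, against 58.0% of the 112 calls.

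**Figure D2:**
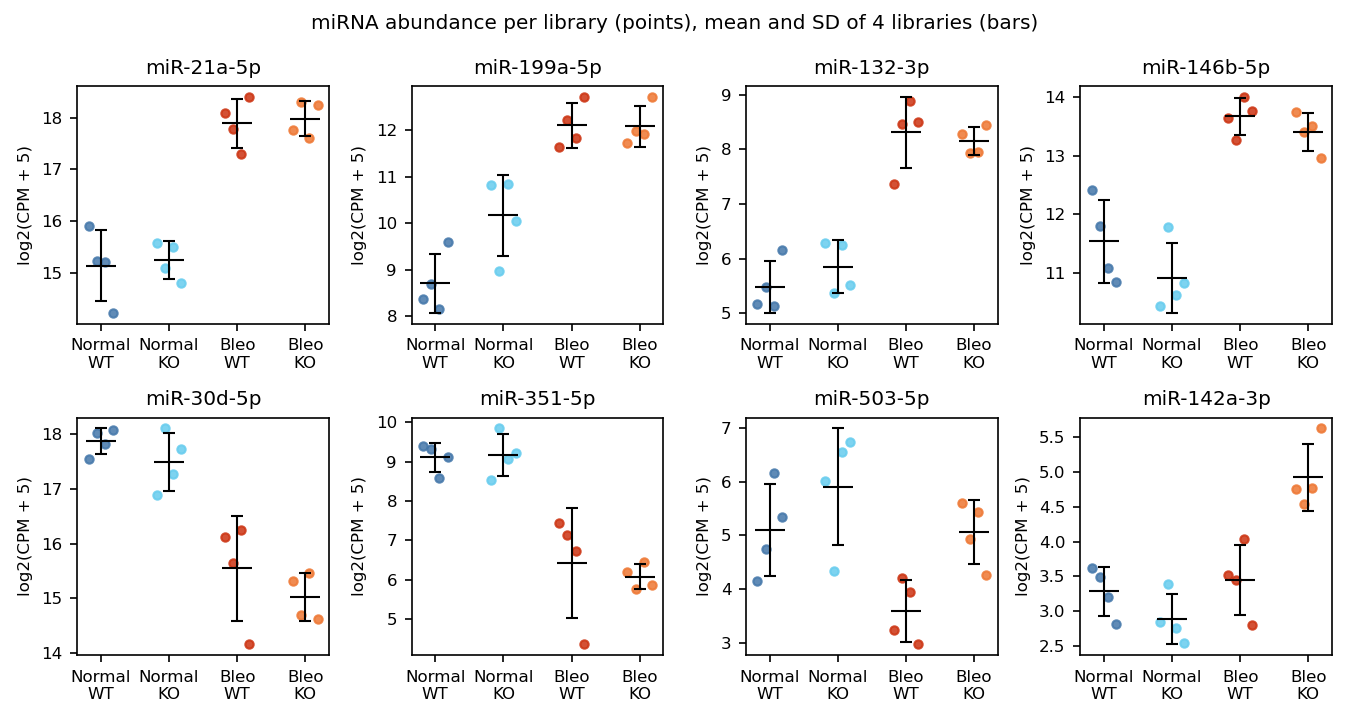
Log2(CPM + 5) of 8 miRNAs in the 4 groups, with 1 point per library and bars for the mean and SD of 4 libraries; each panel has its own axis range. MiR-21a-5p, miR-199a-5p, miR-132-3p and miR-146b-5p are higher and miR-30d-5p and miR-351-5p lower in every bleomycin library than in every normal library of the same genotype, and miR-142a-3p is highest in the 4 bleomycin knockout libraries.

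By list, the injury and inflammation miRNAs rose in wild type: 8 of 12 rose and none fell (8 adjusted over the list alone; fry adjusted p = 4.02e-06; adjusted p = 0.108 with an estimated correlation). They include miR-146b-5p, an NF-kB target (2.13, SE 0.39), miR-34a-5p, a p53 target (1.62, SE 0.38), and miR-155-5p of activated immune cells (1.35, SE 0.40), which was not called without normal library 4 (adjusted p = 0.057). Of the mesenchymal list 7 of 11 rose (7 adjusted over the list alone; adjusted p = 0.032; adjusted p = 0.755 with an estimated correlation). Among them were miR-199a-5p, miR-214-3p (2.34, SE 0.44), miR-199a-3p (2.14, SE 0.56) and miR-214-5p (1.78, SE 0.45). The miR-322 and miR-503 cluster, a run of hairpins on the X chromosome, fell, with 7 of 10 down (8 adjusted over the list alone; adjusted p = 0.00267; adjusted p = 0.526 with an estimated correlation). Among them were miR-351-3p (-2.87, SE 0.37) and miR-450a-5p (-2.08, SE 0.40). The miR-200 family fell, with 4 of 8 down (4 adjusted over the list alone; adjusted p = 0.0364; adjusted p = 0.755 with an estimated correlation). So did the miR-30 family, with 3 of 8 down (3 adjusted over the list alone; adjusted p = 0.0364; adjusted p = 0.755 with an estimated correlation): miR-30d-5p, miR-30e-5p (-2.31, SE 0.41) and miR-30a-5p (-1.68, SE 0.37). Between deeper and shallower samples the median difference of the mesenchymal list was 1.06 in normal and -0.09 in bleomycin samples. It was -0.21 and -1.08 for the miR-200 family, 0.71 and -0.88 for the miR-30 family, and 0.86 and -0.92 for the miR-322 and miR-503 cluster, with opposite signs for the last 2, and 0.22 and -0.26 for the injury and inflammation list. All 325 miRNAs together had a median difference of -0.08 in normal and -0.69 in bleomycin samples, so the lower list medians in deeper bleomycin samples are not particular to these lists. The mesenchymal and miR-200 calls were both lost without normal library 1, 2 or 3 or bleomycin library 1 or 4 (adjusted p 0.064 to 0.0861 and 0.0693 to 0.15). The miR-30 call was lost without any 1 normal library or bleomycin library 1 or 4 (0.0527 to 0.161). With miR-21a-5p removed from the total the miR-200 and miR-30 calls were lost as well (adjusted p = 0.112 for each).

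The other lists did not pass fry in wild type. The leukocyte list went both ways: miR-147-3p (1.51, SE 0.27), miR-150-5p of lymphocytes (1.76, SE 0.56) and miR-155-5p rose, and miR-223-3p of myeloid cells fell (3 up and 1 down of 10, the same adjusted over the list alone; adjusted p = 0.485, and 1.76e-05 for change in either direction). MiR-150-5p was not called without normal library 1 or 4 (adjusted p = 0.0673 and 0.0548) or bleomycin library 3, which also lowered its log2 change to 1.13 (adjusted p = 0.0596), and miR-155-5p not without normal library 4 (adjusted p = 0.057). The miR-34 and miR-449 family, known from multiciliated airway cells, had 1 up and 3 down of 6 (1 up and 4 down adjusted over the list alone; adjusted p = 0.153). The other epithelial list had 2 up, miR-182-5p (1.51, SE 0.42) and miR-183-5p (1.19, SE 0.38), and 2 down, miR-205-5p and miR-375-3p, of 7 (the same adjusted over the list alone; adjusted p = 0.605), with a median of 0.54 and a mean of -0.40. Adjusted p was 0.265 for the endothelial list, 0.0947 for the miR-29 family, 0.0947 for the let-7 family, 0.605 for the miR-17-92 clusters, 0.634 for the erythrocyte list, 0.78 for the liver and muscle list, 0.429 for the Dlk1-Dio3 cluster and 0.0832 for the list from the publication. The miR-34 and miR-449 family (adjusted p = 0.0228), the miR-29 family (0.0244), the let-7 family (0.00327) and the list from the publication (0.0137) passed fry without bleomycin library 3. Under median-of-ratios and quantile scaling the miR-34 and miR-449 family (0.0202 and 0.0276), the miR-29 family (0.0257 and 0.0302) and the list from the publication (0.00689 and 0.00263) passed as well, and under the first so did the other epithelial list (0.0431). The miR-29 family also passed with no filter (0.0183), the miR-34 and miR-449 family with log2 reads as a covariate (0.0365), and the let-7 family without 2 bleomycin libraries (0.0362) and with miR-21a-5p removed from the total (0.0261). MiR-183-5p was not called without normal library 2 or 4 or bleomycin library 2 or 3 (adjusted p 0.0534 to 0.0663), and miR-375-3p not without normal library 1 or 2 or bleomycin library 4 (0.0534 to 0.0682).

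**Figure D3:**
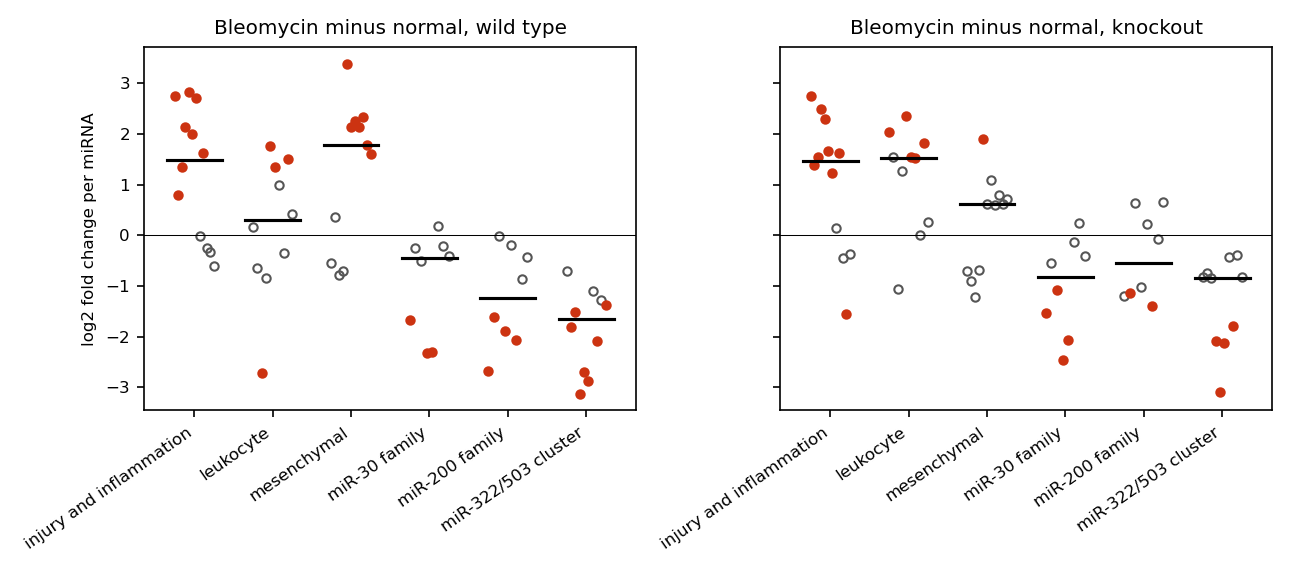
Log2 fold change, bleomycin minus normal, of each tested member of 6 lists in wild type (left) and knockout (right), with filled points for miRNAs past limma's adjusted 0.05, open points for the others and a bar at the list's median. The injury and inflammation list has 8 filled points above 0 in each genotype, with 1 filled below 0 in the knockout, and the miR-322 and miR-503 cluster has 7 filled points below 0 in wild type and 4 in the knockout.

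The second comparison asked the same in the knockout. MiR-21a-5p rose by 2.74 (SE 0.33, adjusted p = 2.65e-05), from 3.96% ± 0.969 (SD, n = 4) of reads to 26.5% ± 6.17. MiR-184-3p rose by 4.08 (SE 0.56, adjusted p = 0.000106), miR-7b-5p by 3.92 (SE 0.40, adjusted p = 4.36e-06), miR-653-5p by 2.53 (SE 0.38), miR-146b-5p by 2.49 (SE 0.39), miR-150-5p by 2.36 (SE 0.56), miR-132-3p by 2.30 (SE 0.39) and miR-199a-5p by 1.91 (SE 0.45), all 7 higher in every bleomycin library than in any normal one. MiR-142a-3p, made in blood cells, rose by 2.04 (SE 0.31, adjusted p = 0.000147), from 2.57 ± 2.0 to 26.7 ± 11.9 CPM. MiR-351-5p fell by 3.10 (SE 0.53, adjusted p = 0.000374) and miR-30d-5p by 2.46 (SE 0.39, adjusted p = 0.000184), from 193235 ± 69374 to 34489 ± 10102 CPM.

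Further rises in the knockout were those of miR-451a (2.89, SE 0.84, adjusted p = 0.0176) and miR-218-5p (1.98, SE 0.54, adjusted p = 0.0119), and further falls those of miR-676-3p (-2.35), miR-503-3p (-2.09), miR-30e-5p (-2.06), miR-1964-3p (-1.91), miR-450a-5p (-1.79), miR-365-3p (-1.63), miR-664-3p (-1.62) and miR-222-3p (-1.56). Among abundant miRNAs let-7i-5p rose (1.04, SE 0.33, adjusted p = 0.0256) and miR-26a-5p fell (-1.07, SE 0.31, adjusted p = 0.0179), neither called by edgeR (adjusted p = 0.0784 and 0.114). MiR-451a was not called without normal library 3 or bleomycin library 4 (adjusted p = 0.0662 and 0.0684), and its log2 change was 3.57 without normal library 1 and 3.52 without bleomycin library 1. MiR-1964-3p was not called without normal library 2 or 4 or bleomycin library 2, 3 or 4 (0.055 to 0.106). Let-7i-5p was not called without normal library 2 or 4 or bleomycin library 1, 2 or 4 (0.0521 to 0.0754), nor miR-26a-5p without normal library 1 or 3 or bleomycin library 1 or 3 (0.0514 to 0.0695). Limma called 76 of 325 miRNAs, 48 up and 28 down, and edgeR 82, 51 up and 31 down. All 325 miRNAs had a median log2 change of 0.11. With miR-21a-5p removed from the total they moved up by a median of 0.37 and the split was 77 up and 19 down. With log2 reads as a covariate the split was 54 up and 60 down, 114 in all.

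Of the injury and inflammation list 8 of 12 rose in the knockout and 1, miR-222-3p, fell (the same adjusted over the list alone; fry adjusted p = 1.46e-05; adjusted p = 0.152 with an estimated correlation). The leukocyte list rose, with 5 of 10 up (5 adjusted over the list alone; adjusted p = 0.0258; adjusted p = 0.74 with an estimated correlation). Among them were miR-142a-3p, miR-150-5p, miR-147-3p (1.82, SE 0.27) and miR-155-5p (1.55, SE 0.40). The miR-322 and miR-503 cluster fell, with 4 of 10 down (4 adjusted over the list alone; adjusted p = 0.0258; adjusted p = 0.74 with an estimated correlation): miR-351-5p, miR-351-3p (-2.13, SE 0.37), miR-503-3p and miR-450a-5p. The miR-30 family fell, with 4 of 8 down (4 adjusted over the list alone; adjusted p = 0.026; adjusted p = 0.74 with an estimated correlation): miR-30d-5p, miR-30e-5p, miR-30a-5p (-1.54, SE 0.37) and miR-30c-5p (-1.09, SE 0.32). The leukocyte list was lower in the deeper samples of both conditions (medians -0.52 in normal and -1.12 in bleomycin, 9 of 10 members in each), and normal knockout had more reads (mean 9366220) than bleomycin knockout (mean 5004910). The leukocyte call was lost without normal library 3 or 4 or bleomycin library 1, 3 or 4 (adjusted p 0.0562 to 0.0908). The miR-30 call was lost without normal library 1, 3 or 4 or bleomycin library 2 or 4 (0.0515 to 0.0908), and the miR-322 and miR-503 call without normal library 3 or 4 or bleomycin library 2 or 4 (0.0526 to 0.0908). MiR-30c-5p was not called without normal library 1, 3 or 4 or bleomycin library 4 (0.0501 to 0.0695). With miR-21a-5p removed from the total the miR-30 call (adjusted p = 0.0645) and the miR-322 and miR-503 call (0.0517) were lost too, as with log2 reads as a covariate (0.067 and 0.0583).

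Among lists that did not pass fry in the knockout, the miR-17-92 clusters, known for their part in proliferation, had 4 up of 8 (4 adjusted over the list alone; adjusted p = 0.111): miR-20a-5p (1.71, SE 0.42), miR-93-5p (1.67, SE 0.45), miR-106b-5p (1.64, SE 0.36) and miR-17-5p (1.62, SE 0.39). The other epithelial list had 3 up of 7 (3 up and 1 down adjusted over the list alone; adjusted p = 0.174), among them miR-182-5p (1.89, SE 0.42) and miR-183-5p (1.43, SE 0.38). Both lists passed fry under median-of-ratios scaling (adjusted p = 0.00261 for each) and with miR-21a-5p removed from the total (0.0101 and 0.0115). Under median-of-ratios scaling the miR-200 family (0.043) and the miR-29 family (0.00849) passed too, and under quantile scaling the miR-17-92 clusters (0.00197), the other epithelial list (0.00382) and the miR-29 family (0.0181). With no filter the miR-17-92 clusters (0.0232), the miR-29 family (0.0146) and the list from the publication (0.0133) passed. So did the last with miR-21a-5p removed from the total (0.0144), the miR-17-92 clusters without 2 bleomycin wild-type libraries (0.0252) and the endothelial list, downward, without the 3 normal samples of low depth (0.0471). The miR-200 family had 2 down of 8 (2 adjusted over the list alone; adjusted p = 0.492). Of these miR-141-3p fell by 1.39 (SE 0.37). The mesenchymal list had 1 up of 11, miR-199a-5p (1 adjusted over the list alone; adjusted p = 0.639). Adjusted p was 0.492 for the endothelial list, 0.932 for the miR-34 and miR-449 family, 0.124 for the miR-29 family, 0.45 for the let-7 family, 0.219 for the erythrocyte list, 0.639 for the liver and muscle list, 0.852 for the Dlk1-Dio3 cluster, whose median changed sign under another scaling, and 0.125 for the list from the publication. That list had a median of -0.17 and a mean of 0.34, its test pointed up, and its median also changed sign under another scaling. The miR-17-92 list passed fry without bleomycin library 2 (adjusted p = 0.0475) and the miR-29 list without normal library 2 (0.0453).

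Set side by side, the bleomycin effects of both genotypes were alike in direction. Across the 325 miRNAs, which are not independent replicates, the log2 changes in wild type and knockout had a Pearson correlation of 0.784 and a Spearman correlation of 0.774, and 80.3% had the same sign. Of the calls, 37 miRNAs rose in both, where 9.60 are expected if calls fell independently, 19 fell in both, where 4.05 are expected, and 0 were called in opposite directions. Averaged over genotypes limma called 149 miRNAs, 77 up and 72 down, and edgeR 177. Among miRNAs above 50 CPM the smallest p belonged to miR-21a-5p (2.75, SE 0.24, adjusted p = 1.43e-07) with miR-21c (2.68), whose profile tracks it, then miR-7b-5p (3.30, SE 0.29), miR-653-5p (2.55, SE 0.27) and miR-184-3p (3.74, SE 0.40). With miR-21a-5p removed from the total the split was 120 up and 42 down.

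**Figure D4:**
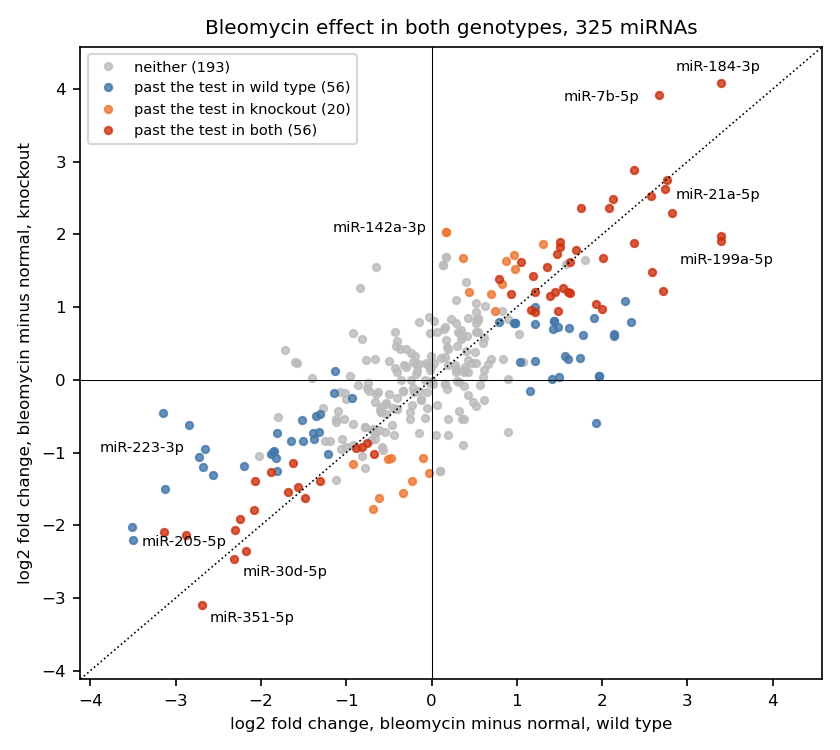
Log2 fold change, bleomycin minus normal, of the 325 tested miRNAs in wild type (x axis) and knockout (y axis), coloured by the genotype in which limma called them, with a dotted line of equal change. The Pearson correlation across miRNAs is 0.784, and miR-142a-3p (0.16 in wild type, 2.04 in knockout) lies away from the line.

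In that averaged comparison 7 lists passed fry: injury and inflammation (adjusted p = 1.37e-07; 8 of 12 up and 1 down, the same adjusted over the list alone), leukocyte (0.0266; 5 up and 1 down of 10, likewise) and mesenchymal (0.036; 7 up and 2 down of 11, likewise) upward. Downward were the miR-322 and miR-503 cluster (0.000488; 8 of 10 down, likewise), the miR-30 family (0.00467; 4 of 8, likewise), the miR-29 family (0.0266; 2 of 4, likewise) and the miR-200 family (0.036; 4 of 8, likewise). The other epithelial list (adjusted p = 0.168) had a median of 0.60 and a mean of -0.12, and its test pointed up. It passed under median-of-ratios (0.00108) and quantile scaling (0.00271), without bleomycin wild-type library 1 (0.046) and with miR-21a-5p removed from the total (0.00317). The miR-17-92 clusters (adjusted p = 0.0901) passed under both scalings (0.00191 and 0.00118), with miR-21a-5p removed (0.00317), with no filter (0.0314), and without bleomycin wild-type library 1 (0.0221), bleomycin knockout library 2 (0.0468) or 2 bleomycin wild-type libraries (0.0466). The let-7 family (0.0694) passed with miR-21a-5p removed (0.00317), with no filter (0.0431), and without bleomycin wild-type library 3 (0.00256) or 2 bleomycin wild-type libraries (0.0169). The miR-34 and miR-449 family (0.264) passed under median-of-ratios scaling (0.028) and with log2 reads as a covariate (0.025). None of the 7 passed camera, with adjusted p from 0.148 to 0.858 with an estimated correlation. The calls of the injury and inflammation list, the miR-322 and miR-503 cluster and the miR-30 family held without any 1 library. Leaving out 1 library ended the leukocyte call (normal wild type 3, normal knockout 4, bleomycin knockout 1, 3 or 4, adjusted p 0.0528 to 0.0588) and the miR-29 call (normal wild type 3, normal knockout 4, bleomycin wild type 4, bleomycin knockout 2 or 4, 0.0516 to 0.0621). It also ended the miR-200 call (normal wild type 1, 2 or 3, normal knockout 2, 3 or 4, bleomycin wild type 4, bleomycin knockout 1, 2 or 4, 0.0557 to 0.0892) and the mesenchymal call (normal wild type 1, 2 or 3, normal knockout 4, bleomycin wild type 3 or 4, any 1 bleomycin knockout library, 0.0516 to 0.0868).

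The third comparison asked what loss of syndecan-1 did in the normal lung. Among miRNAs above 50 CPM the smallest p belonged to miR-26b-5p (log2 1.37, SE 0.40), with 614 ± 139 CPM (SD, n = 4) in wild type and 1728 ± 720 in knockout, miR-199a-5p (1.46, SE 0.45), let-7i-5p (1.04, SE 0.33), miR-199a-3p (1.71, SE 0.56) and miR-199b-3p (1.71, SE 0.57), each with a limma adjusted p of 0.222 and each higher in 3 of 4 knockout libraries than in any wild-type library. The exception in each case was knockout library 2, the normal knockout library with the fewest reads, 2753095. Limma called 0 of 325 miRNAs, with 58 at an unadjusted p under 0.05, and edgeR called 0, with 67. Without knockout library 2 limma called 64, but the low-depth normal samples then left, libraries 1 and 2, were both wild type. Limma called 0 without the 3 normal samples of low depth, which leaves wild-type libraries 3 and 4. With log2 reads as a covariate it also called 0. No list passed fry, with adjusted p from 0.604 to 0.903. The miR-17-92 clusters had a median of 0.02, which changed sign under another scaling, and a mean of -0.17, and the Dlk1-Dio3 cluster a median of -0.08 and a mean of 0.03. The smallest was that of the endothelial list (4 of 4 adjusted over the list alone, log2 median 1.38) and the mesenchymal list (4 of 11 adjusted over the list alone, median 0.87). The 4 endothelial members are only 2 signals. MiR-126a-5p and miR-126b-3p have identical values, and miR-126a-3p and miR-126b-5p nearly so. Both lists were called without knockout library 2 (adjusted p = 0.0186 for each). The same 2 lists were higher in the 5 deeper normal samples than in the 3 shallower ones by medians of 2.07 and 1.06.

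The fourth comparison, on which the series title bears, asked what loss of syndecan-1 did after bleomycin. MiR-142a-3p, specific to blood cells, rose in the knockout by 1.47 (SE 0.31, 95% interval 0.83 to 2.12, limma adjusted p = 0.023), from 6.42 ± 3.84 to 26.7 ± 11.9 CPM (SD, n = 4). Every knockout library, between 18.3 and 44.3 CPM, lay above every wild-type library, between 1.99 and 11.3 CPM. It was 1 of 2 calls among 325 miRNAs. The other was miR-142b, whose values are identical. Among other miRNAs above 50 CPM the smallest p belonged to miR-34b-5p (1.51, SE 0.46, adjusted p = 0.252), miR-450b-5p (1.74, SE 0.56, adjusted p = 0.315), miR-542-3p (1.74, SE 0.59, adjusted p = 0.333), miR-10b-5p (-1.28, SE 0.53, adjusted p = 0.537) and miR-101a-3p (0.98, SE 0.42, adjusted p = 0.537). MiR-503-5p had 7.75 ± 4.94 CPM in wild type and 30.4 ± 13.3 in knockout (1.47, SE 0.52, adjusted p = 0.382). In the 4 bleomycin samples with the most reads miR-450b-5p was 1.23 and miR-542-3p 1.37 lower in log2 than in the other 4, where all 325 miRNAs had a median difference of -0.69. In normal samples the deeper had 1.61 and 1.68 more of them. EdgeR called 0 miRNAs, with 31 at an unadjusted p under 0.05 against 28 by limma, and gave miR-142a-3p an adjusted p of 0.0881. The miR-142a-3p call was lost without bleomycin wild-type library 1, 2 or 4 or bleomycin knockout library 1, 3 or 4 (adjusted p 0.05 to 0.0915). It was also lost with a pseudocount of 1, with only the 8 libraries compared and with the replicate block. Over the alternatives run for it its adjusted p ran from 0.000625 to 0.179.

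Of the 4 miRNAs recalled from the publication, 3 were tested, and all 3 were higher in the bleomycin knockout: miR-142a-3p, miR-34b-5p and miR-503-5p (1 called, 3 adjusted over the list alone; fry adjusted p = 0.00154; adjusted p = 0.0217 with an estimated correlation), which is not independent evidence if, as recalled, the study chose them on these libraries. The membership of this list was not checked against the publication. The last, miR-144-3p of red cells, was below the filter, with 13 reads in bleomycin wild type (0.923 ± 0.673 CPM, SD, n = 4) and 112 in bleomycin knockout (5.98 ± 3.37). The miR-322 and miR-503 cluster, to which miR-450b-5p, miR-542-3p and miR-503-5p belong, had 5 of 10 members up adjusted over the list alone and none over all miRNAs (adjusted p = 0.417). No other list passed fry, with adjusted p from 0.417 to 0.86. Among the abundant miRNAs miR-21a-5p differed by 0.09 (SE 0.33, adjusted p = 0.948) and miR-30d-5p by -0.52 (SE 0.39, adjusted p = 0.694).

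The interaction asked whether the bleomycin effect differed between genotypes. MiR-142a-3p had the smallest p, with an effect larger in the knockout by 1.87 (SE 0.43, limma adjusted p = 0.0671, 0.000506 to 0.373 over the alternatives). Among miRNAs above 50 CPM the smallest p belonged to miR-100-5p (-2.51, SE 0.85), miR-1298-5p (2.69, SE 0.97), miR-214-3p (-1.54, SE 0.63), miR-195a-3p (-1.62, SE 0.66) and miR-223-3p (1.67, SE 0.70), each with an adjusted p of 0.623. The difference between the mesenchymal list's rise in wild type and its values in the knockout was not past fry (adjusted p = 0.373), nor was that of the leukocyte list (0.373), the miR-200 family (0.481) or the list from the publication (0.0908). Limma called 0 miRNAs, with 24 at an unadjusted p under 0.05, and edgeR 0, with 30. Limma called 2, miR-142a-3p and miR-142b, without normal wild-type library 4, normal knockout library 2 or bleomycin wild-type library 3. The mesenchymal list passed fry without normal knockout library 2 (adjusted p = 0.0465), the leukocyte list without bleomycin wild-type library 3 (0.0416), and the list from the publication without bleomycin wild-type library 3 (0.0162) or bleomycin knockout library 2 (0.032). That list also passed with no filter (0.0255), under median-of-ratios (0.00831) and quantile scaling (0.00753), without 2 bleomycin wild-type libraries (0.0479) and with miR-21a-5p removed from the total (0.031).

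Averaged over conditions, the knockout effect had its smallest p, among miRNAs above 50 CPM, for miR-26b-5p (1.06, SE 0.28), miR-101a-3p (1.02, SE 0.30), miR-542-3p (1.41, SE 0.41), miR-450b-5p (1.30, SE 0.39) and miR-34b-5p (1.06, SE 0.32), each with a limma adjusted p of 0.125. Limma called 0 miRNAs, with 67 at an unadjusted p under 0.05, and edgeR 0, with 79. Limma called 37 without normal knockout library 2 and 4 without bleomycin wild-type library 2. It called 1 without the 3 normal samples of low depth and 0 with log2 reads as a covariate. The list from the publication passed fry (0 called, 3 adjusted over the list alone; adjusted p = 0.00859; adjusted p = 0.273 with an estimated correlation), again not as independent evidence, and no other list did (adjusted p from 0.451 to 0.928). The other epithelial list had a median of 0.09 and a mean of -0.16, and the leukocyte list a median of -0.01, which changed sign under another scaling, and a mean of 0.03. Across miRNAs the knockout effects in normal and bleomycin libraries had a Pearson correlation of 0.289 and a Spearman correlation of 0.321.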

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

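The tests of counting noise, of GC content in bleomycin samples and of regrouped libraries were written before their results were seen, and the other tests in this part were chosen after the patterns were seen. Of 512 groups of 4 libraries, for 121 named miRNAs and 7 measures per library in each of 4 study groups, 21 had 1 library far from the other 3 by Dixon's ratio, and chance flags about 1 in 20 groups. The number is therefore no larger than chance allows.

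Libraries far above the other 3 of their group, in CPM with the range of the others, were these. In normal knockout library 2 they were miR-184-3p 17.1 (1.87 to 2.85), miR-433-3p 13.8 (1.69 to 2.74) and miR-222-3p 809 (632 to 654). In normal wild-type library 4 they were miR-199a-3p 1830 (500 to 549), miR-199b-3p 631 (162 to 186) and miR-199b-5p 737 (182 to 214). In normal wild-type library 3 they were miR-200a-3p 63300 (39000 to 41500), miR-182-5p 1660 (1010 to 1090) and miR-29b-3p 57.5 (30.9 to 31.5). In normal knockout library 4 they were miR-29a-3p 6360 (5220 to 5350) and miR-141-5p 44.7 (29.4 to 31.6), and in bleomycin knockout library 1 miR-434-3p 22.6 (10.8 to 11.7).

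Libraries far below the other 3 were normal knockout library 4 for miR-7b-5p, 2.95 (4.36 to 4.52), normal wild-type library 4 for miR-223-3p, 140 (216 to 236), and normal wild-type library 3 for miR-676-3p, 179 (716 to 875). Others were normal knockout library 2 for miR-106b-5p, 15.3 (24.3 to 25.6), bleomycin wild-type library 1 for miR-206-3p, 14.4 (85.4 to 114), and bleomycin wild-type library 3 for miR-26b-5p, 498 (912 to 1010). In the bleomycin knockout they were library 2 for miR-34c-5p, 3820 (11000 to 13200), library 1 for miR-664-3p, 16.2 (28.3 to 28.8), and library 4 for miR-145a-5p, 223 (278 to 278).

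Between deeper and shallower samples of 1 condition, 123 miRNAs differed in normal samples (46 higher and 77 lower in the deeper) and 139 in bleomycin samples (11 higher and 128 lower). In bleomycin samples this was in part a shift of the whole profile one way. The median was -0.69 over 325 miRNAs with 78.8% below 0, against -0.08 and 52.3% in normal samples. With that median taken out, the median absolute log2 difference in bleomycin samples was 0.518, against 0.752 before. The deeper bleomycin samples held 28.0 to 34.8% miR-21a-5p and the shallower 16.1 to 22.7%. As the values are shares, more of miR-21a-5p lowers the other miRNAs, but how much of the shift this accounts for was not tested. The differences in both conditions correlated across miRNAs with a Pearson value of 0.413. Noise from counting reads was excluded as the cause, because thinning deep libraries to the smallest depth of their condition moved miRNAs little. The median move was 0.102 of the observed difference in normal and 0.0615 in bleomycin samples. Thinning draws reads, so the sampling of molecules before amplification was not tested. Recovery that depends on GC content could not be told apart from other causes, with a Spearman rho across 256 miRNAs of -0.128 (95% interval -0.254 to -0.00668) in normal and -0.0752 (-0.211 to 0.0582) in bleomycin samples. In shallow normal samples miR-451a, also of red cells, differed by 0.0563 (SE 0.77) where miR-486a-5p differed by 2.93 (SE 0.87), a gap of 2.87 (SE 1.16). This argues against red cell RNA as the whole cause of the higher miR-486a-5p there. It does not exclude that, since miR-486a-5p was picked after its difference was seen. No other source of the difference in cells was tested, and the labels give no group that follows depth.

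For the higher miR-142a-3p in the bleomycin knockout, error from counting reads was excluded, because 511 reads against 84 gave a ratio of pooled CPM of 5.01 with a lower 95% bound of 3.97. More vesicles from leukocytes could not be told apart from a change in miR-142a-3p alone. The other 9 leukocyte miRNAs had a median log2 difference of 0.406, 8 of them above 0. Its SE of 0.175 came from resampling these miRNAs and does not measure the spread between libraries. Between libraries the SE of single members ran from 0.27 to 0.69. The leukocyte share of reads was 0.365% ± 0.228 in bleomycin wild type and 0.383% ± 0.0969 in bleomycin knockout (exact permutation p = 0.914).

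The rise of miR-21a-5p lowers the share of all other miRNAs, and with it removed from the total the falls had a median log2 change of -1.48 in wild type (median SE 0.46, -1.83 before) and -1.16 in the knockout (median SE 0.37, -1.44 before). The removal moved all miRNAs up by a median of 0.35 in wild type and 0.37 in the knockout. Before it, the median log2 change of all 325 miRNAs was already near 0, at -0.004 in wild type and 0.11 in the knockout. The fall of abundant miR-30d-5p (-2.32 and -2.46) raises the share of the others and was left in the total. The values after removal are therefore not a corrected version of the first ones. The smallest called falls were -0.68 and -0.86. The falls had been chosen as called, so their median could not come near 0 and this test could not decide. It shows only that a shift of this size is smaller than each called fall. The measure set first, the share of falls that stayed called, had left the question open and was replaced after its result was seen. Of the 47 and 28 falls 34 and 19 stayed called, and those that ended had a median of -1.06 in wild type (-1.31 before) and -0.76 in the knockout (-1.14 before). Their calls ended because the change shrank while the median SE hardly moved (0.46 before and after in wild type, 0.37 and 0.36 in the knockout), and only let-7f-1-3p in wild type and miR-574-3p in the knockout lay within 2 SE of 0.

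When the libraries were regrouped, 1 of 35 splits, the real one, gave as many calls as the real 112 for bleomycin in wild type (highest other 34). The same held for the knockout, with 1 of 35 splits (76, highest other 1), and for both averaged, with 1 of 100 (149, highest other 100). The smallest share that these splits can give is 0.029 for 35 and 0.01 for 100. Regrouping therefore argues against chance for the bleomycin effect but cannot exclude it. For the knockout effect in bleomycin libraries chance was left open, with 3 of 35 splits (2, highest other 104). For the knockout effect in normal libraries, the interaction and the averaged knockout effect the real count was 0, so every split, 35 of 35, 100 of 100 and 100 of 100, had as many by construction, and the splits say nothing about chance there (highest others 79, 86 and 56). The split with 79 calls set normal wild-type libraries 1, 2 and 4 and knockout library 2 against the rest, and so follows the 3 shallow normal samples. That with 104 calls set bleomycin wild-type libraries 1 and 4 and knockout libraries 2 and 4, the 4 deepest, against the 4 shallowest.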

How the results depend on the processing

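Of the tests here, those without 3 normal or 2 bleomycin wild-type libraries, with log2 reads as a covariate, without miR-21a-5p in the total and with identical profiles counted once were chosen after the result was seen, and the others before. Of 182 comparisons of a count of calls with its alternatives 148 stayed within 1.5 times the first count, 17 were weaker and 17 stronger. Of 2708 for lists 2429 kept their side of the threshold and their sign, 98 were weaker and 60 stronger, and 121 changed sign without being called. Of 6967 for named miRNAs 6358 kept both, 227 were weaker, 205 stronger and 2 reversed, and 175 changed sign without being called. Results that were not called at first and stayed so, and counts of 0 that stayed 0, are among those kept. Only a called result could become weaker, and between 0 and 7 of the 16 lists were called per comparison. With a 100 CPM filter, which tests only 174 miRNAs, the bleomycin counts were 60 in wild type, 38 in the knockout and 81 averaged, and the knockout count after bleomycin was 0. With array weights (0.237 to 3.66) the counts were 187 for bleomycin in the knockout, 191 for the knockout in normal, 4 for the knockout after bleomycin, 102 for the interaction and 119 for the averaged knockout effect, and miR-126a-3p and miR-126b-5p, which share their values, turned to -1.084 in the bleomycin knockout (adjusted p = 0.0238); the cause was not tested. The knockout count after bleomycin was 0 with a pseudocount of 1, with only the 8 libraries compared and with edgeR, 4 without a filter, and 1 with identical profiles counted once, since miR-142b then drops out. The interaction count was 2 without 2 bleomycin wild-type libraries, with log2 reads as a covariate and without miR-21a-5p in the total. The averaged knockout count was 1 with a pseudocount of 20 and without the 3 shallow normal libraries, which also left 67 calls for bleomycin in wild type. Apart from the filter, the identical profiles and the left-out libraries, the cause was not tested.

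Without 1 library of the groups compared at a time the counts ran from 74 to 134 for bleomycin in wild type, 57 to 78 in the knockout and 126 to 164 averaged, from 0 to 64 for the knockout in normal, 0 to 2 after bleomycin and 0 to 37 averaged, and from 0 to 2 for the interaction. Leaving out a library of another group, which changes only the pooled spread, gave up to 85 calls for bleomycin in the knockout (without bleomycin wild-type library 3) and 3 for the knockout after bleomycin (without normal knockout library 2). With the replicate block the counts were 105 and 72 for bleomycin in wild type and knockout, 0 for the knockout in normal and after bleomycin, 0 for the interaction, 150 for averaged bleomycin and 0 for the averaged knockout. Libraries share only a number: 7 of 16 same-number correlations were over 0.1, and 4 of 16 libraries correlated best with their own number. Depth limits the low end, where 1 read in the shallowest library is 0.913 CPM.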

Other observations

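The tests of the arms of hairpins were chosen after the results for single miRNAs were seen. Both arms of a hairpin come from 1 precursor, and in 33 of 79 hairpins with both arms tested their ratio changed after bleomycin, averaged over genotypes (limma, adjusted over hairpins). In 24 the 5p arm gained on the 3p arm and in 9 the 3p arm gained. Of 4 miR-30 hairpins 3 changed: miR-30d-5p fell by 2.39 while miR-30d-3p changed by 0.02 (log2 ratio -2.41, SE 0.42, adjusted p = 4e-04), miR-30a-5p fell by 1.61 while miR-30a-3p changed by 0.03 (-1.63, SE 0.17, adjusted p = 5.47e-06), and miR-30e-5p fell by 2.19 and miR-30e-3p by 0.40 (-1.78, SE 0.19, adjusted p = 5.47e-06). The ratio of miR-30b was not called (-0.53, SE 0.39, adjusted p = 0.266). MiR-223-3p fell by 1.89 while miR-223-5p changed by 0.22 (2.10, SE 0.33, adjusted p = 0.000262), and miR-34b-3p fell by 2.77 while miR-34b-5p changed by -0.62 (2.15, SE 0.44, adjusted p = 0.00147).

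A pseudocount of 5 shrinks the change of an arm of few CPM. With a pseudocount of 0.5, 29 of the 33 ratios stayed called with the same sign. The ratio of miR-21a, whose 3p arm is of few CPM, was among those that ended (1.67 with a pseudocount of 5, 0.86 and adjusted p = 0.055 with 0.5). Of the 21 hairpins with both arms at 50 CPM or more in every group, 10 were called, 4 toward 5p and 6 toward 3p, so the excess toward 5p was not seen there.

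Hairpins with an arm identical in every library to another miRNA were then left out. Of the other 74 ratios 31 changed, 23 toward 5p and 8 toward 3p, and 11 were called in wild type and in the knockout separately. Hairpins with only nearly identical arms, such as the 3p arms of miR-199a and miR-199b, were kept. With log2 reads as a covariate 38 ratios were called, among them all 33. Between genotypes 0 ratios were called in normal libraries, 0 after bleomycin and 0 for the interaction, and 1 averaged over conditions, that of miR-34b (2.19, adjusted p = 0.0132).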
